A study of Mus musculus with 8 samples.

How the data were processed

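Poly(A)-selected RNA of 8 samples, 2 biological replicates in each of 4 groups, was made into TruSeq libraries and sequenced as paired ends on a HiSeq instrument, per the labels' protocols. The protocol speaks of 4 cDNA libraries with 2 biological replicates; this was read as 4 groups with 2 replicates each because 8 samples are listed. The labels name the replicates as biological without saying whether they came from separate animals, so the authors' tests measure the spread between these cultures. Per the submitters' processing notes, the tools included FastQC 0.11.5, Trimmomatic 0.35, STAR 2.5.2, Cufflinks and Cuffdiff, the latter with no version, on GRCm38; which options were set is not given in the sources used here.

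The authors deposited a Cuffdiff table for each genotype with 39175 genes, per the file headers. Its FPKM values are 1 number per gene and group, pooled over the replicates by the authors. Each table also holds the authors' test statistic, a signed score, and the authors' p-value and q-value for UV against untreated cells. The smallest p the authors' test gave was 5e-05, shared by 4685 genes in p53KO and 4926 in p53CryKO cells, so genes at that value are not ranked by it. Genes with a status other than OK in the authors' deposited tables were left out: 23313 and 23292 not tested, 5 and 10 with too many fragments, and 0 and 1 failed. Another deposited table, which repeats genes tested in both genotypes, was not used. Each genotype was normalized in its own table, so tests stay within a table.

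The log2 fold change was recomputed from the authors' FPKM, because 1565 and 1621 cells of the deposited column hold no number. For 15527 and 15518 tested genes with a number in both, it differed from the deposited value by at most 1.42e-05 and 5.04e-05. No pseudocount was added, so genes listed at 0 in a condition have no fold change; 95 and 87 of the called genes are of this kind. The standard error was taken as the size of the log2 fold change divided by the size of the test statistic. A normal quantile of the authors' p exceeded the test statistic by a median factor of 1.44 in p53KO and 1.44 in p53CryKO cells, so this error is on the wide side.

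A gene was called in a UV comparison at q of 0.05 or less in the authors' deposited table. The difference between the genotypes was tested as the difference of the log2 fold changes over its standard error, against a normal distribution, with Benjamini-Hochberg adjustment over 12300 genes that were tested in both tables and had FPKM of 1 or more in a group. On simulated data for that comparison and those 12300 genes, with 200 changed, 1.70% were recovered at a log2 difference of 1, 59.6% at 2 and 79.7% at 3. At the largest p that was called, a gene of median error needed a difference of 1.91. The test therefore misses differences of the size of 1.

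Gene lists, 32 in number with 870 entries, were fixed before the data were examined, as were the tests, the naming rule and the first set of other settings. All entries were found, 6 of them through the gene ID of the GENCODE annotation. Lists with at least 4 measured members were tested with cameraPR of limma 3.58.1 in R 4.3.3 on ranks of the log2 fold change, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. The background was tested genes with FPKM of 1 or more in a condition and a finite fold change, 11951 in p53KO and 11783 in p53CryKO cells. On simulated data for the p53KO comparison over 11951 genes, 96.7% of lists of 25 genes shifted by 1.5 were recovered. List members were simulated without correlation, and neither smaller shifts nor the list test of the difference were simulated. The figure therefore does not say how often lists with smaller shifts would be missed.

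Named genes were the 8 largest rises and 8 largest falls of each UV comparison among called genes with FPKM of 5 or more in the higher condition and above 0 in the lower, and likewise for the difference, without models named Gm and a number, names ending in Rik, or names of several genes. From each list came up to 4 called members with the largest change, or up to 2 of highest FPKM where none was called, and a fixed set of p53, clock and apoptosis genes was added; the text names part of these. Gene spans and exonic lengths came from GENCODE M21 of GRCm38, which held 96.2% of the gene IDs. Of 22812 loci that held a single gene, 82.2% matched that annotation within 200 bases at both ends. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

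That first set of other settings held stricter thresholds, a minimum fold change, filters on FPKM, centring on the median, errors taken from the p-value, a preset correlation of 0.05, log2 fold changes with a pseudocount of 1, and 10000 random lists matched on mean FPKM. The random lists were drawn gene by gene, so they allow for no correlation among list members. Other scalings, a rescaled standard error, annotated lengths and list tests after removing the trend with exonic length in 20 bins were added after seeing the data.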

Results

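RNA from mouse embryonic fibroblasts of the C57BL/6J background was profiled after poly(A) selection. The cells came from p53-/- animals, called p53KO here, and from p53-/-Cry1-/-Cry2-/- animals, called p53CryKO. Trp53 encodes the tumour suppressor p53, and Cry1 and Cry2 encode the cryptochromes, which repress transcription in the circadian clock. Cells were either left untreated or given 40 J/m2 of light from a germicidal lamp at 254 nm and harvested 16 h later. Each of the 4 groups had 2 biological replicates, 8 samples in all. The deposited tables hold 1 pooled FPKM (fragments per kilobase, scaled for library size) per gene and group, with the authors' Cuffdiff test of UV against untreated cells within each genotype, so no value per replicate and no SD can be given. FPKM values below are those of the authors' deposited table, and log2 fold changes were recomputed from them. Errors below are standard errors implied by the authors' test statistic.

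Total counts per sample are unknown. Among the low nonzero values of transcripts of 2 to 10 kb, the peak of FPKM times kb was taken as the worth of a single fragment. That reading was not checked. This step was 0.0108 FPKM times kb in untreated and 0.0204 in UV-treated p53KO cells, a ratio of 1.89. In p53CryKO cells it was 0.00945 and 0.0179, a ratio of 1.90. On that reading, a fragment counted for more in the UV-treated groups under the authors' scaling. A transcript of 2 kb at an FPKM of 1 corresponds to about 186 such steps in untreated and 98.1 in UV-treated p53KO cells.

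The targeted genes were read first. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873 of GRCm38) had FPKM values of 78.8 and 95.0 in untreated and UV-treated p53KO cells and 84.4 and 106 in cells labelled p53CryKO, where the authors' test failed. Cry1 (ENSMUSG00000020038, chromosome 10, 85131700 to 85185064) stood at 3.85 and 4.55 in p53KO cells and at 3.34 and 3.79 in cells labelled p53CryKO. Cry2 (ENSMUSG00000068742, chromosome 2, 92403646 to 92434043) stood at 2.44 and 0.488 against 4.54 and 1.10. Transcripts of all 3 targeted genes were thus counted in the groups labelled as lacking them. An FPKM over the whole gene does not show which part was deleted, so these values do not check the genotype labels, and every statement on p53KO and p53CryKO cells below rests on the labels.

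The first question was which transcripts changed after UV in cells labelled p53KO. In the authors' deposited table, 8065 of 15857 tested genes passed q of 0.05 in p53KO cells, 3796 higher and 4269 lower after UV. The largest falls among genes that met the naming rule were in Gas1, a membrane protein linked to growth arrest (60.3 to 1.57 FPKM, log2 fold change -5.27, implied SE 0.31), Ralgds, an exchange factor for Ral GTPases (-5.05), Mrgprf (-4.72), Pcyox1l (-4.70), Ccnf, which encodes cyclin F (31.7 to 1.23 FPKM, -4.69, implied SE 0.32), Cdc42ep2 (-4.63), Chst12 (-4.52) and the adrenergic receptor gene Adra1d (-4.32). The largest rises were in Alox8, a lipoxygenase (0.0922 to 15.7 FPKM, 7.41, implied SE 1.22), the mitochondrial ribosomal RNAs mt-Rnr1 (96.0 to 15208 FPKM, 7.31, implied SE 0.35) and mt-Rnr2 (5.29), the small nuclear RNA Rn7sk (1.97 to 203 FPKM, 6.69, implied SE 0.54), Thap1 (5.83), Arl5c (5.04), Lars2, a mitochondrial tRNA synthetase (4.69) and the histone gene Hist1h3i (4.49). For each of these 16 genes, q in the authors' deposited table was between 0.000169 and 0.000903.

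In p53CryKO cells, 8300 of 15872 tested genes passed q of 0.05 in the authors' deposited table, 3984 higher and 4316 lower. The largest falls were in Adra1d (5.63 to 0.211 FPKM, log2 fold change -4.74, implied SE 0.50), Pcyox1l (-4.69), Ccnf (32.8 to 1.55 FPKM, -4.40, implied SE 0.28), Gas1 (26.9 to 1.29 FPKM, -4.38, implied SE 0.29), Hs3st1 (-4.28), Cdc42ep2 (-4.18), Tsku (-4.17) and Smad6, an inhibitor of BMP signalling (-3.99). The largest rises were in Rn7sk (1.46 to 243 FPKM, 7.38, implied SE 0.56), mt-Rnr1 (187 to 19434 FPKM, 6.70, implied SE 0.21), Rnu3a (5.98), Thap1 (4.40), mt-Rnr2 (4.30), Lars2 (4.27), mmu-mir-6236 (4.27) and Neat1, the long noncoding RNA of paraspeckles (22.2 to 302 FPKM, 3.77, implied SE 0.29). The q of these 16 genes, which met the naming rule, lay between 0.000161 and 0.0368 in the authors' deposited table. Alox8 rose here as well (0.0652 to 4.66 FPKM, log2 fold change 6.16, implied SE 1.51) but stayed below the FPKM of 5 that the rule asks for.

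The split into higher and lower genes depends on the scale. The authors' scaling left the median log2 fold change of genes with FPKM of 1 or more at 0.05 in p53KO and 0.05 in p53CryKO cells, while the summed FPKM of protein-coding genes rose from 506401 to 1018530 and from 529537 to 1074560. The groups were also scaled to equal total fragments, a choice made after seeing the data that lowers every log2 fold change by 0.78 and 0.79. The sum of FPKM times exonic length over genes with an annotated length stood in for the unknown fragment totals. On that scale 1483 genes were higher and 7000 lower in p53KO cells, and 1402 and 7404 in p53CryKO cells. Scaled to equal coding FPKM, a shift of 1.01 and 1.02, 1074 were higher and 7943 lower in p53KO cells and 972 and 8489 in p53CryKO cells. Rises and falls in the text are therefore changes relative to the median gene. The list tests rank genes and do not move with a common shift. Of all background genes of those tests, 3469 rose and 3790 fell of 11951 in p53KO cells, and 3611 rose and 3766 fell of 11783 in p53CryKO cells. Counts of called list members below are to be read beside these shares.

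Transcripts of the cytosolic ribosome rose together. In p53KO cells 44 rose and 0 fell of 45 measured ribosomal protein genes (median log2 fold change 1.83, cameraPR adjusted p = 6.9e-13), and in p53CryKO cells 43 rose and 0 fell of 44 (1.67, adjusted p = 4.65e-13). Rplp1 went from 5840.3 to 27239.8 FPKM in p53KO and from 6908 to 27972 in p53CryKO cells, Rps20 from 773 to 3781 and from 869 to 3676, and Rpl5 from 288 to 1789 and from 413 to 1521. Replication-dependent histone genes, whose messages end in a stem-loop in place of a poly(A) tail, 26 rose and 1 fell of 28 measured in p53KO cells (2.77, adjusted p = 4.73e-11) and 27 rose and 1 fell of 30 in p53CryKO cells (2.40, adjusted p = 6.65e-11). Their levels were low, and with a pseudocount of 1 the medians were 1.21 and 1.23: Hist1h4a went from 0.313 to 6.58 FPKM and from 0.275 to 4.83, Hist2h4 from 0.140 to 3.21 and from 0.126 to 1.59, and Hist1h2ac from 0.0909 to 1.51 and from 0.236 to 2.89. Ribosomal protein and histone genes share sequence with many near-identical copies, so how fragments were divided among copies is uncertain. Both groups are short transcripts, and the shortest 10% of protein-coding genes by exonic length had a median log2 fold change of 0.87 in p53KO and 0.93 in p53CryKO cells, which turned negative at equal coding FPKM. With the trend with length removed, ribosomal protein genes were still called (medians 1.26 and 1.15, adjusted p = 6.74e-10 and 2.91e-10), as were histone genes (medians 1.45 and 0.79). Among RNAs without a long poly(A) tail, mt-Rnr1, mt-Rnr2 and Rn7sk rose. Few small RNA models passed the authors' test singly: 3 of 13 snRNA and 2 of 67 snoRNA and scaRNA models rose in p53KO cells. Most still had positive log2 fold changes, 13 of 13 and 51 of 67 in p53KO cells (medians 2.58 and 1.17). In p53CryKO cells these were 15 of 15 and 63 of 72 (medians 3.11 and 1.63).

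Interferon-stimulated genes rose as a list. In p53KO cells 15 rose and 1 fell of 21 measured (median 1.79, adjusted p = 0.000207) and in p53CryKO cells 26 rose and 1 fell of 33 (1.87, adjusted p = 1.26e-06). Irf7, a transcription factor of the interferon response, went from 0.888 to 9.10 FPKM in p53KO and from 3.07 to 18.3 in p53CryKO cells, Oas1a from 0.740 to 6.47 and from 4.52 to 18.1, and Xaf1 from 1.82 to 15.7 and from 15.9 to 58.2. With a pseudocount of 1 the list medians were 1.18 and 1.03. The member that fell in both was Irf1 (17.3 to 1.53 and 23.3 to 3.35 FPKM).

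Wnt pathway genes fell as a list. 1 rose and 20 fell of 24 measured in p53KO cells (median -1.51, adjusted p = 7.32e-05) and 1 rose and 14 fell of 19 in p53CryKO cells (-1.35, adjusted p = 0.000648). Axin1, a scaffold of the beta-catenin destruction complex, went from 32.6 to 5.79 FPKM and from 30.7 to 4.12, and the receptor gene Fzd7 from 5.75 to 1.09 and from 7.44 to 0.997. Axin1 acts against the pathway and Fzd7 within it. With a pseudocount of 1 the Wnt medians were -0.92 and -0.98. Cholesterol synthesis genes, 2 rose and 13 fell of 23 measured in p53KO cells (-1.34, adjusted p = 0.000851), and 1 rose and 13 fell of 23 in p53CryKO cells (-0.82, adjusted p = 0.0129). The squalene epoxidase gene Sqle went from 52.7 to 3.17 FPKM and from 38.1 to 2.93, Hmgcs1 from 31.3 to 2.47 and from 26.9 to 3.75, and Dhcr7 from 10.2 to 0.706 and from 8.98 to 1.93. With a preset correlation of 0.05 the cholesterol list missed the threshold in p53CryKO cells (adjusted p = 0.1004).

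**Figure D1:**
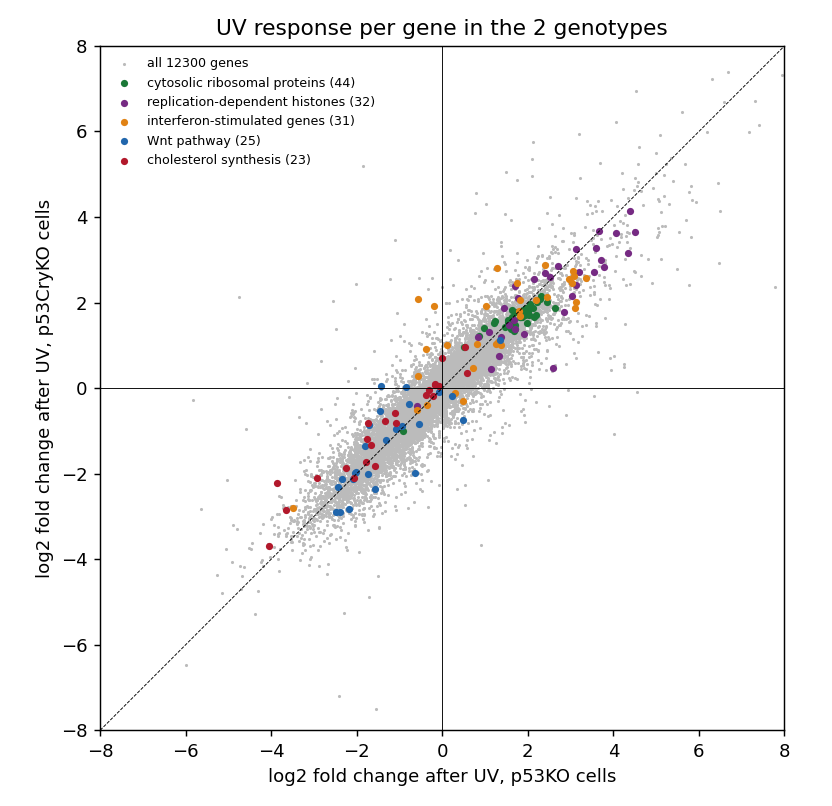
Log2 fold change after UV in p53KO cells (horizontal axis) and p53CryKO cells (vertical axis), 1 point per gene for 12300 genes with a test in both genotypes and FPKM of 1 or more in a group, with 5 lists in colour and the line of equal change dashed. Ribosomal protein and histone genes lie at the upper right and most Wnt and cholesterol genes at the lower left, on the authors' scaling; the correlation across genes is 0.919.

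Clock genes were read because the cryptochromes act in the clock. In p53KO cells 1 rose and 8 fell of 17 measured (median -0.66, adjusted p = 0.0768), and in p53CryKO cells 0 rose and 14 fell of 17 (-1.0, adjusted p = 0.00136). The list was called in p53CryKO cells and missed the threshold in p53KO cells, but this contrast did not hold: the p53CryKO call was lost against random matched lists (adjusted p = 0.115), and the p53KO list was called among genes with FPKM of 5 or more (adjusted p = 0.0233). Its test of the difference gave a median difference of -0.20 with adjusted p = 0.424, and 0 of 19 members differed. Per2, a repressor in the clock, went from 0.844 to 0.118 FPKM (log2 fold change -2.84, implied SE 0.45) and from 4.45 to 0.685 (-2.70, implied SE 0.29), and both changes passed in the authors' deposited table. Cry2 likewise fell in both genotypes (-2.32 and -2.05), as did Tef (-2.57 and -1.39), Nfil3 (-0.65 and -1.61) and Bhlhe40 (-1.73 and -0.95). Rora rose in p53KO cells (0.428 to 1.85 FPKM) and did not pass in p53CryKO cells (0.0697 to 0.141, q = 0.248 in the authors' deposited table). Arntl, which encodes BMAL1, passed in p53CryKO cells (0.883 to 0.289 FPKM) and not in p53KO cells (3.63 to 2.83, q = 0.160 in the authors' deposited table). Per1 passed in p53CryKO cells (4.22 to 1.95 FPKM, with 3.91 to 2.48 in p53KO cells), as did Nr1d1 (7.21 to 3.60, with 17.3 to 16.4) and Per3 (2.26 to 0.450, with 1.44 to 0.356). Dbp did not pass in either (4.54 to 2.38 and 4.92 to 2.59), nor did Cry1. Harvest came at a single time, so the phase of the clock is not known.

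**Figure D2:**
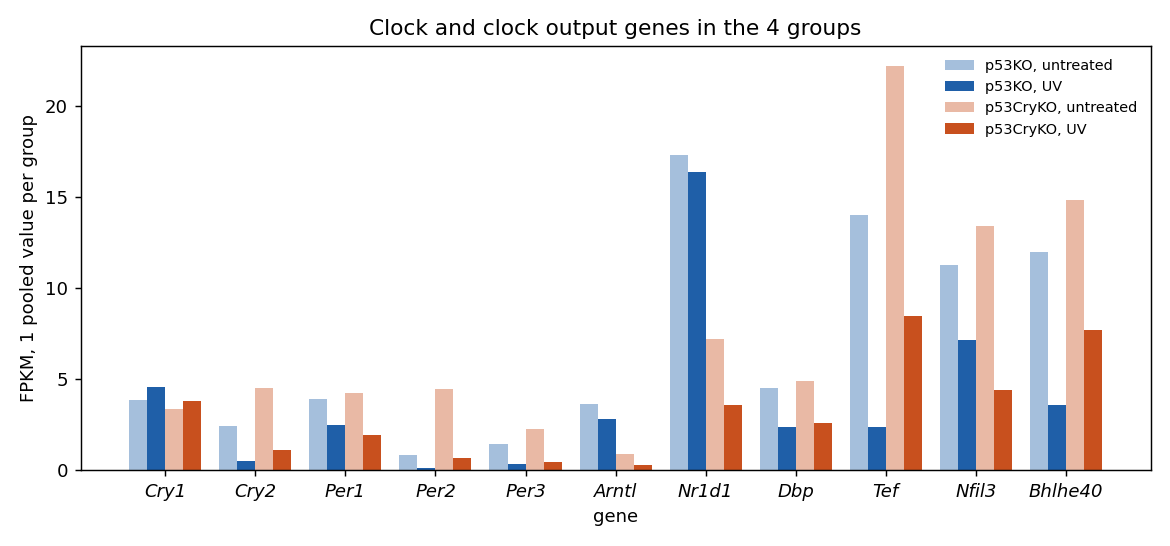
Pooled FPKM (vertical axis) of 11 clock and clock output genes in the 4 groups, pale bars for untreated and full bars for UV-treated cells, with no error bars because the tables hold 1 value per group. Per2 and Cry2 are lower after UV in both genotypes, at 0.118 and 0.488 in p53KO and 0.685 and 1.10 in p53CryKO cells; levels of the genotypes come from tables normalized separately.

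Cell death and p53 targets bear on the question in the series title, whether cryptochrome loss raises apoptosis after UV. Of the p53 target list, 7 rose and 10 fell of 24 measured in p53KO cells (median log2 fold change -0.27, cameraPR adjusted p = 0.597) and 6 rose and 12 fell of 25 in p53CryKO cells (-0.37, adjusted p = 0.345). The members with the largest changes went both ways: Btg2 (2.46 and 1.78) and Pmaip1, which encodes the BH3-only protein Noxa (1.43 to 6.43 and 0.443 to 1.32 FPKM), rose, while Sesn1 (-3.12 and -3.23) and Phlda3 (-1.96 and -1.96) fell. Cdkn1a, the cell cycle inhibitor p21, rose from 4.21 to 6.67 FPKM in p53KO and from 0.809 to 4.23 in p53CryKO cells, a difference of 1.72 (implied SE 0.49) that missed the threshold (adjusted q = 0.129), and in p53KO cells its direction turned under both other scalings. Bbc3, which encodes Puma, fell (-0.75 and -0.77), and Mdm2 passed in p53CryKO cells (-0.76) and not in p53KO cells (-0.27). Of the mitochondrial apoptosis list, 6 rose and 9 fell of 25 measured in p53KO cells (median log2 fold change -0.47, cameraPR adjusted p = 0.463) and 7 rose and 12 fell of 25 in p53CryKO cells (-0.53, adjusted p = 0.532). Cycs, cytochrome c, rose (83.9 to 389 and 96.4 to 351 FPKM), while the antiapoptotic Bcl2l1 (-2.57 and -2.53) and the proapoptotic Bid (-2.15 and -2.51) fell. Of the death receptor list, 4 rose and 9 fell of 15 measured in p53KO cells (median log2 fold change -0.86, cameraPR adjusted p = 0.240) and 4 rose and 9 fell of 16 in p53CryKO cells (-0.60, adjusted p = 0.317). Tnfrsf1a, a receptor for TNF, fell from 60.1 to 10.6 and from 39.3 to 10.2 FPKM. None of the 3 lists was called by cameraPR for a difference between the genotypes: the median difference was -0.39 for p53 targets (adjusted p = 0.120), 0.07 for mitochondrial apoptosis (adjusted p = 0.669) and 0.27 for death receptors (adjusted p = 0.138). Against random lists matched on FPKM, however, the p53 target list was called for a more negative response in p53CryKO cells (adjusted p = 0.00435), so its result depends on the test. Trp73 was listed at 0 in the 4 groups. Of the 4 genes in the list of p53 relatives and Egr1, 1 rose (Egr1) and 1 fell of 3 measured in p53KO cells and 1 rose of 1 in p53CryKO cells, too few for a list test.

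Stress and signalling lists changed in members without being called as lists by cameraPR. Most background genes were called too, so a count of called members alone does not set a list apart. Of the immediate-early and AP-1 list, 11 rose and 10 fell of 28 measured in p53KO cells (median log2 fold change -0.01, cameraPR adjusted p = 0.753) and 9 rose and 14 fell of 28 in p53CryKO cells (-0.55, adjusted p = 0.794). Egr1 rose in both genotypes (37.1 to 98.0 and 3.83 to 32.6 FPKM), as did Fosb (2.65 and 3.30), and Fosl2 fell (-2.81 and -2.73). Of the integrated stress and unfolded protein response list, 12 rose and 7 fell of 26 measured in p53KO cells (median log2 fold change 0.41, cameraPR adjusted p = 0.412) and 12 rose and 8 fell of 25 in p53CryKO cells (0.26, adjusted p = 0.799). Atf3 rose (2.03 to 20.8 and 2.77 to 9.10 FPKM), as did Ppp1r15a (2.78 and 1.93), and Cebpb fell (-1.99 and -1.43). Of the NF-kB target, cytokine and chemokine list, 7 rose and 11 fell of 23 measured in p53KO cells (median log2 fold change -0.18, cameraPR adjusted p = 0.837) and 8 rose and 9 fell of 22 in p53CryKO cells (0.17, adjusted p = 0.914). Cxcl12 fell from 312 to 154 and from 259 to 87.9 FPKM. Of the NRF2 and oxidative stress list, 13 rose and 7 fell of 31 measured in p53KO cells (median log2 fold change 0.18, cameraPR adjusted p = 0.597) and 16 rose and 7 fell of 30 in p53CryKO cells (0.49, adjusted p = 0.282). Gpx4 and Mt1 rose (1.91 and 1.75 in p53KO, 1.82 and 1.90 in p53CryKO cells) and Gclc fell (-2.41 and -2.56). Of the heat shock protein list, 4 rose and 4 fell of 19 measured in p53KO cells (median log2 fold change 0.30, cameraPR adjusted p = 0.597) and 6 rose and 6 fell of 19 in p53CryKO cells (0.23, adjusted p = 0.799). Hspb1 and Hsp90aa1 rose (2.12 and 1.97 in p53KO, 2.45 and 1.57 in p53CryKO cells), and Hspa1b fell (-2.11 and -1.78). Of the receptor tyrosine kinase and growth factor list, 8 rose and 14 fell of 29 measured in p53KO cells (median log2 fold change -0.55, cameraPR adjusted p = 0.376) and 3 rose and 12 fell of 24 in p53CryKO cells (-0.62, adjusted p = 0.0887). Erbb2 fell (8.25 to 0.819 and 5.34 to 0.664 FPKM), as did Pdgfa, a platelet-derived growth factor (-3.20 and -2.01). Of the senescence and growth arrest list, 7 rose and 13 fell of 24 measured in p53KO cells (median log2 fold change -0.86, cameraPR adjusted p = 0.376) and 7 rose and 11 fell of 23 in p53CryKO cells (-0.69, adjusted p = 0.321). The senescence list was called as lower against random matched lists in both genotypes (adjusted p = 0.000933 and 0.0134), as was the heat shock list in p53CryKO cells (0.0399), although its median was positive. Gadd45a rose (15.3 to 128 and 9.20 to 51.2 FPKM), and Lmnb1, which encodes lamin B1, fell (38.5 to 4.12 and 44.5 to 5.11 FPKM). The rank test pointed up for immediate-early genes in p53KO cells and down for NF-kB targets in p53CryKO cells, opposite in sign to the medians. Positive medians in this paragraph turned negative under both other scalings.

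DNA repair and the cell cycle gave mixed changes on the authors' scaling alone, and their counts too are to be read beside the shares of all background genes. Of the nucleotide excision repair list, the pathway that removes UV photoproducts, 8 rose and 8 fell of 27 measured in p53KO cells (median log2 fold change 0.03, cameraPR adjusted p = 0.854) and 10 rose and 7 fell of 27 in p53CryKO cells (0.24, adjusted p = 0.933). Cdk7 and Ercc2, subunits of TFIIH, fell (-2.09 and -1.93 in p53KO, -2.15 and -2.36 in p53CryKO cells), as did Ercc4 (-1.75 and -1.75) and Ercc6 (-1.56 and -2.01). Of the homologous recombination, Fanconi and checkpoint list, 5 rose and 15 fell of 36 measured in p53KO cells (median log2 fold change -0.28, cameraPR adjusted p = 0.597) and 6 rose and 12 fell of 36 in p53CryKO cells (0.03, adjusted p = 0.532). Xrcc2 and the checkpoint mediator gene Mdc1 fell (-2.13 and -2.06 in p53KO, -1.81 and -1.30 in p53CryKO cells). Of the DNA replication list, 11 rose and 15 fell of 40 measured in p53KO cells (median log2 fold change -0.21, cameraPR adjusted p = 0.597) and 14 rose and 13 fell of 40 in p53CryKO cells (0.10, adjusted p = 0.914). Against random matched lists it was called as lower in p53KO cells (adjusted p = 0.0287). Ung, a uracil-DNA glycosylase, fell from 13.9 to 1.97 and from 11.5 to 2.95 FPKM. Of the mitosis list, 13 rose and 13 fell of 43 measured in p53KO cells (median log2 fold change 0.06, cameraPR adjusted p = 0.993) and 13 rose and 11 fell of 43 in p53CryKO cells (0.05, adjusted p = 0.914). Cdk1 fell from 275 to 25.4 FPKM in p53KO and from 273 to 61.6 in p53CryKO cells and Aurkb from 52.5 to 13.2 and 43.3 to 15.6, while Ndc80 rose from 8.10 to 28.3 and 9.46 to 24.9. The positive medians of these lists turned negative under both other scalings, and the rank test pointed down in each case where the median was positive. At equal coding FPKM nearly all called members were lower: higher and lower were 0 and 16 in p53KO and 1 and 18 in p53CryKO cells for excision repair, 1 and 24 in p53KO and 0 and 26 in p53CryKO cells for recombination, 1 and 26 in p53KO and 0 and 27 in p53CryKO cells for replication and 1 and 28 and 0 and 36 for mitosis.

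Lists of matrix, contractile, glycolysis and mitochondrially encoded genes were not called by cameraPR in the UV comparisons either. With the trend with exonic length removed, a test added after seeing the data, collagen and fibroblast matrix genes were called as higher (adjusted p = 0.0204) and mitochondrially encoded genes as lower (0.0258) in p53KO cells. Of the collagen and fibroblast matrix list, 15 rose and 9 fell of 37 measured in p53KO cells (median log2 fold change 0.35, cameraPR adjusted p = 0.523) and 12 rose and 9 fell of 35 in p53CryKO cells (0.09, adjusted p = 0.996). Postn and Dcn rose (298 to 1261 and 17.1 to 79.0 FPKM in p53KO, 63.4 to 253 and 26.5 to 99.1 in p53CryKO cells), and Thbs1 fell (436 to 96.8 and 216 to 30.4). Of the matrix metalloproteinase and inhibitor list, 8 rose and 8 fell of 21 measured in p53KO cells (median log2 fold change -0.16, cameraPR adjusted p = 0.705) and 4 rose and 9 fell of 20 in p53CryKO cells (-0.05, adjusted p = 0.532). Mmp9 rose in p53KO cells (2.32 to 9.72 FPKM) and stood at 0.667 and 1.13 in p53CryKO cells. Of the contractile and TGF-beta-responsive list, 9 rose and 15 fell of 30 measured in p53KO cells (median log2 fold change -0.67, cameraPR adjusted p = 0.410) and 9 rose and 16 fell of 31 in p53CryKO cells (-0.72, adjusted p = 0.129). Against random matched lists it was called as lower in both genotypes (adjusted p = 0.000933 and 0.00140). Id1 fell from 242 to 26.0 and 178 to 22.2 FPKM, and Cyr61 from 456 to 91.2 and 422 to 55.8. Of the glycolysis and hypoxia list, 7 rose and 5 fell of 23 measured in p53KO cells (median log2 fold change 0.32, cameraPR adjusted p = 0.753) and 10 rose and 7 fell of 25 in p53CryKO cells (0.09, adjusted p = 0.933). The glucose transporter gene Slc2a1 fell (25.8 to 2.43 and 20.5 to 2.36 FPKM) and Pgk1 rose (133 to 357 and 153 to 369). Of the mitochondrially encoded messages, 1 rose and 1 fell of 9 measured in p53KO cells (median log2 fold change 0.23, cameraPR adjusted p = 0.854) and 4 rose and 1 fell of 9 in p53CryKO cells (0.37, adjusted p = 0.445). The authors' test left mt-Co1 and 4 other mitochondrial genes out in both genotypes because of too many fragments. Positive list medians here also turned negative under both other scalings, and for glycolysis in p53CryKO cells the rank test pointed down.

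Few of the listed markers of other cell types were measured, but not all of those were low, with Krt19 at 409.7 FPKM in untreated p53CryKO cells. Of the immune markers 3 rose and 1 fell of 4 measured in p53KO cells and 2 rose and 1 fell of 3 in p53CryKO cells, with Cd68, a macrophage marker, at 2.41 to 12.5 and 2.82 to 11.3 FPKM. Endothelial markers gave 2 higher and 0 lower of 3 in p53KO and 1 and 0 of 3 in p53CryKO cells. Epithelial and keratinocyte markers gave 1 and 0 of 2, and 4 and 1 of 6, with Krt8 at 1.93 to 5.76, Krt14 at 4.95 to 8.97 and Krt19 at 409.7 to 605 FPKM in p53CryKO cells. Muscle markers gave 1 and 0 of 4, and 2 and 0 of 4, with the cardiac troponin gene Tnnt2 at 15.9 to 30.5 and 7.08 to 19.7 FPKM. Medians above 0 of endothelial, epithelial and muscle markers turned negative at equal coding FPKM. Neural and glial markers gave 0 called of 2 in each genotype, Map2 and Tubb3. Adipocyte, cartilage and bone markers gave 1 and 4 of 8, and 2 and 3 of 5, with Sox9 lower (-2.41 and -1.95) and Fabp4 higher (1.22 and 1.30). Where these lists had 4 or more measured members, cameraPR gave adjusted p = 0.412 for immune, 0.523 for muscle and 0.410 for adipocyte, cartilage and bone markers in p53KO cells, and 0.345 for epithelial, 0.144 for muscle and 0.790 for adipocyte, cartilage and bone markers in p53CryKO cells. Adjusted over the list alone, the count of called members was the same for 24 of the 32 lists in p53KO and 22 in p53CryKO cells and rose by at most 2 in the others.

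**Figure D3:**
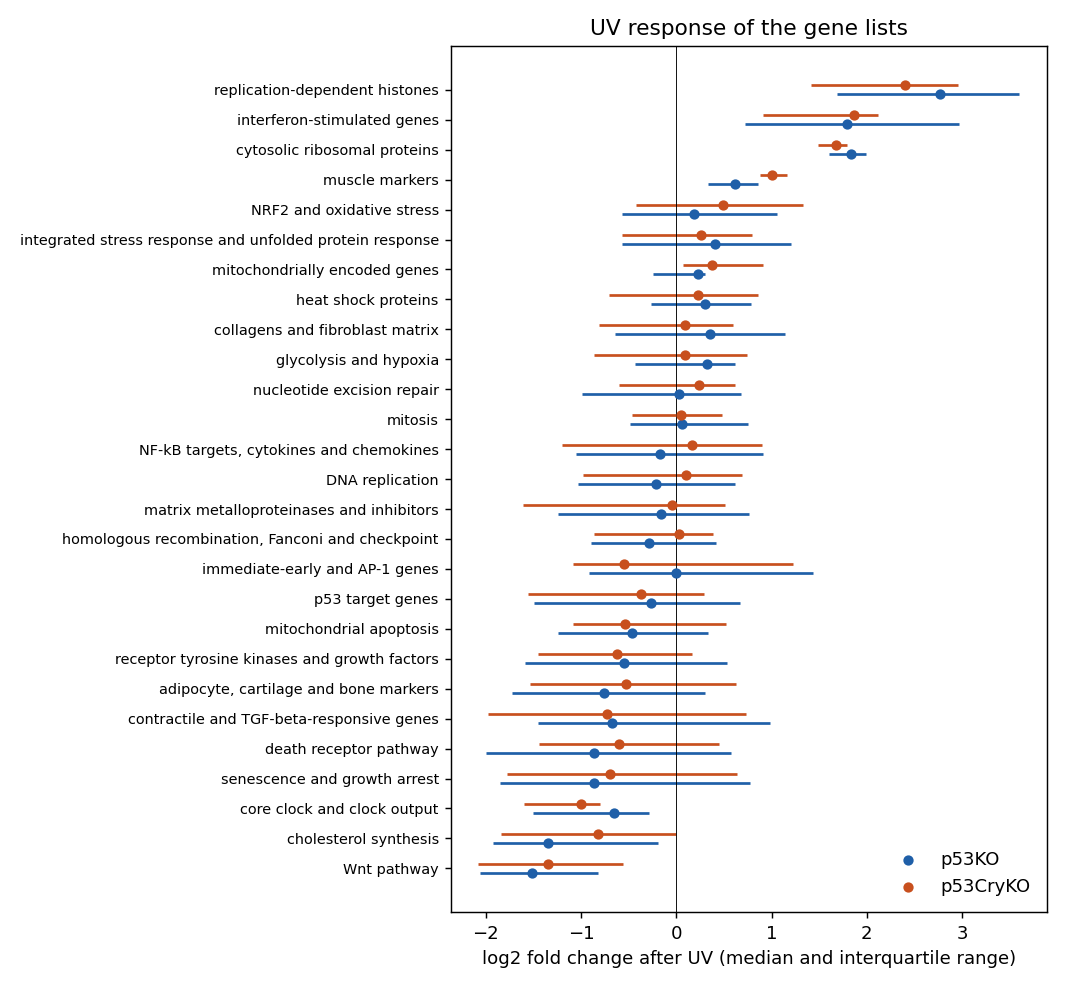
Median log2 fold change after UV (point) and interquartile range (bar) of the measured members of each list with at least 4 in both genotypes, on the authors' scaling. The median of ribosomal protein genes is 1.83 in p53KO and 1.67 in p53CryKO cells and that of Wnt genes -1.51 and -1.35; of the positive medians drawn, those of the histone, interferon and ribosomal protein lists stay positive in both genotypes when the groups are scaled to equal coding FPKM, and the others turn negative.

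The second question was whether the UV response differs between the genotypes. Across 12300 genes tested in both, the log2 fold changes of p53KO and p53CryKO cells had a Pearson correlation of 0.919 and a Spearman correlation of 0.930, across genes, which are not independent replicates. Of the genes higher after UV, 2998 were called in both genotypes, against 1043 for independent lists, and of those lower, 3381 against 1216. The comparisons share no control libraries. 2099 genes were called in 1 genotype and not the other, and the test of the difference itself called 10 of them. These counts differ in stringency. The UV calls used the authors' p, while the difference used the implied errors, wider by a median factor of 1.44 in each genotype. Across the 12300 genes the difference over its error had an SD of 0.83, narrower than the normal distribution assumed. The rescaled error was not run for the difference, so 10 of 2099 does not show that the genotypes responded alike. A gene of median error needed a difference of 1.91 to be called, so smaller differences would be missed.

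The difference of the fold changes (p53CryKO minus p53KO) passed an adjusted q of 0.05 for 22 genes, 9 with a more positive and 13 with a more negative response in p53CryKO cells. Immediate-early genes stood on both sides. Egr3 went from 3.04 to 6.16 FPKM in p53KO and from 0.249 to 4.92 in p53CryKO cells (difference 3.29, SE 0.62, q = 0.000233), and Egr1 differed by 1.68 (SE 0.39, q = 0.0121). Klf4 went from 1.24 to 3.28 FPKM in p53KO and from 12.8 to 6.78 in p53CryKO cells (difference -2.31, SE 0.43, q = 0.000233), and the MAP kinase phosphatase gene Dusp6 differed by -1.58 (q = 0.0202). Other positive differences were in Ifit3, an interferon-stimulated gene (0.767 to 0.514 and 1.97 to 8.34 FPKM, difference 2.66, q = 0.00267), Prl2c3 (2.36), Sprr1a, a cornified envelope protein (2.04), H3f3a, a histone H3.3 gene (1.92), and Chchd2 (1.61). Other negative differences were in Arl4d (-2.54), Zcchc3 (-2.53), Edn1, which encodes endothelin-1 (1.15 to 3.01 and 8.78 to 4.23 FPKM, -2.44), Adamts1 (-1.79), Plk2, a p53 target (27.8 to 31.8 and 87.3 to 29.0 FPKM, -1.78), and Rgs16 (-1.59). Zcchc3 went from 0.166 to 0.621 FPKM in p53KO and from 9.59 to 6.21 in p53CryKO cells, so its p53KO fold change rests on low values. H3f3a, Chchd2 and Prl2c3 have near-identical copies in the genome, so their values are uncertain. Cyclin B kinase Cdk1, for which the difference was 1.29, missed the threshold (q = 0.507).

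As lists, cholesterol synthesis genes fell less in p53CryKO cells (median difference 0.34 over 23 genes, cameraPR adjusted p = 0.00209) and integrated stress and unfolded protein response genes had more negative responses (median difference -0.28 over 26, adjusted p = 0.00871). Both calls were lost with a preset correlation of 0.05, with adjusted p = 0.0664 and 0.144. No correlation could be estimated, since the tables hold no values per library. The other lists missed the threshold, with adjusted p = 0.117 for histones, 0.982 for interferon-stimulated genes, 0.159 for ribosomal proteins, 0.982 for the Wnt pathway, 0.283 for immediate-early genes, 0.846 for NF-kB targets, 0.143 for NRF2, 0.982 for heat shock proteins, 0.982 for nucleotide excision repair, 0.982 for homologous recombination, 0.283 for replication and 0.982 for mitosis. They were 0.0866 for collagens, 0.669 for metalloproteinases, 0.108 for contractile genes, 0.982 for glycolysis, 0.108 for mitochondrially encoded genes, 0.312 for growth factors, 0.159 for senescence, 0.822 for immune, 0.159 for endothelial, 0.117 for muscle and 0.425 for adipocyte, cartilage and bone markers. The sign of the rank test was opposite to that of the median for nucleotide excision repair, interferon-stimulated genes, the Wnt pathway and glycolysis. Of list members, 2 immediate-early genes had a more positive and 2 a more negative response, as did 1 interferon-stimulated gene (Ifit3, positive), 1 p53 target (Plk2, negative) and 1 metalloproteinase gene (Adamts1, negative). Adjusted over the list alone, the count of differing members was the same for 26 lists and rose by at most 3, for immediate-early genes.

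Untreated levels are set side by side without a test, since each genotype was normalized in its own table. 507 of the 12300 genes were at least 4-fold apart. The interferon list was higher in untreated p53CryKO cells for 26 of 31 members (median log2 ratio 1.68). Cholesterol genes were higher there for 1 of 23 (median -0.56) and collagen genes for 9 of 36 (median -0.61). Of cell-type markers, epithelial and keratinocyte genes were higher there for 3 of 3 (median 2.71) and adipocyte, cartilage and bone genes for 1 of 6 (median -1.04). Egr1 stood at 37.1 FPKM in untreated p53KO and 3.83 in untreated p53CryKO cells, Sprr1a at 199 and 4.74, Per2 at 0.844 and 4.45, and Arntl at 3.63 and 0.883.

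UV lesions stop RNA polymerase, so fold changes were set against gene length. Across genes, the Spearman correlation of log2 fold change with the locus length given in the tables was -0.183 in p53KO and -0.222 in p53CryKO cells. Up to 183 genes share 1 locus in the tables, so lengths from the GENCODE annotation were added after seeing the data. Among protein-coding genes of p53KO cells the median fell from 0.87 in group 1 of 10, the shortest by exonic length, to -0.49 in group 9 and -0.37 in group 10, and in p53CryKO cells from 0.93 to -0.48 and -0.43. By genomic span the medians ran from 0.68 to -0.28 and from 0.70 to -0.31; all of these medians are negative at equal coding FPKM.

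**Figure D4:**
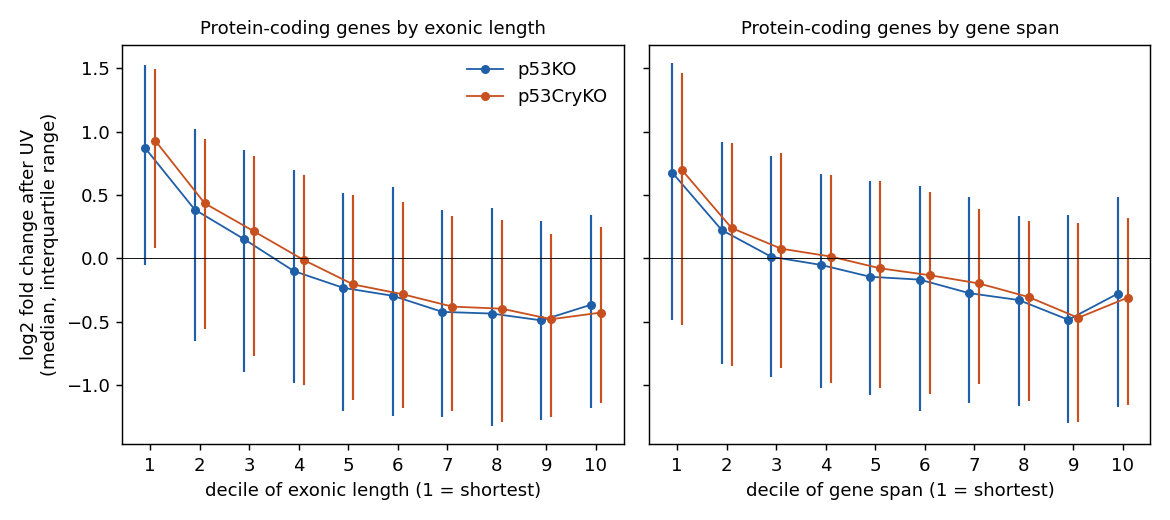
Median log2 fold change after UV (points) and interquartile range (bars) of protein-coding genes in 10 groups of exonic length (left) and genomic span (right), in p53KO and p53CryKO cells, on the authors' scaling. Group 1 by exonic length sits at 0.87 and 0.93, group 9 at -0.49 and -0.48, and the interquartile ranges of neighbouring groups overlap; the positive medians turn negative at equal coding FPKM.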

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

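The genotypes differed in 22 genes and 2 lists by the test of the difference itself (p53CryKO minus p53KO log2 fold change). More negative in p53CryKO cells were the pseudogene Gm5560 (-4.59), Arl4d (-2.54), Zcchc3 (-2.53), Edn1 (-2.44), Spin4 (-2.39), Klf4 (-2.31), Ranbp6 (-2.01), Dusp8 (-1.98), 9930013L23Rik (-1.96), Adamts1 (-1.79), Plk2 (-1.78), Rgs16 (-1.59) and Dusp6 (-1.58), and the integrated stress and unfolded protein response list (median -0.28). More positive were Chchd2 (1.61), Egr1 (1.68), the pseudogene Gm9800 (1.72), H3f3a (1.92), Sprr1a (2.04), Prl2c3 (2.36), Ifit3 (2.66), Agt (2.82) and Egr3 (3.29), and the cholesterol synthesis list (median 0.34). Gm5560, Spin4, Ranbp6, Dusp8, 9930013L23Rik, Gm9800 and Agt fall outside the naming rule and were named after their values were seen.

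All tests of explanations in this part were chosen after the results were seen. If differing genes had unequal untreated levels and closer levels after UV, the untreated ratio between the genotypes would exceed the UV ratio in size. It did so for 11 of 22 genes (exact binomial p = 1.00, two-sided), which leaves both readings open for the set. The set was mixed, so this count cannot speak for single genes. The log2 ratio of p53CryKO over p53KO went from -3.61 untreated to -0.32 after UV for Egr3 and from 3.36 to 1.05 for Klf4. It went from 1.36 to 4.02 for Ifit3 and from 0.03 to 1.95 for H3f3a. Another candidate source is a difference between the cultures apart from the Cry genes. 507 of 12300 genes were at least 4-fold apart untreated, and with the replicates pooled into 1 value per genotype, culture and genotype cannot be told apart. Cryptochrome loss, the biological explanation the design names, remains open and untested beyond the label.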

How the results depend on the processing

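Scalings to equal fragments or equal coding FPKM, a rescaled error, annotated lengths and length-adjusted list tests were chosen after the data were seen. No paired analysis was possible because the tables hold 1 pooled value per group; the planned fit of replicate values with a replicate block, with each replicate left out or with a pseudocount of 0.1 was not run for the same reason. Depth is known only as a relative step, which limits statements on genes of low FPKM. The counts of genes changed by UV stayed within 1.5 times under every setting run except a minimum log2 fold change of 1 in p53CryKO cells (5348), which removes smaller changes by construction. The totals hide exchange: at equal coding FPKM 5412 of 8065 genes in p53KO and 5701 of 8300 in p53CryKO cells were shared, and at equal fragments 5634 and 5650. These shared counts disregard direction, so a gene higher on the authors' scaling and lower after the shift counts as shared. The 22 differing genes became 14 at q of 0.01. With errors from the p-value there were 39, of which 14 were among the 22. The authors' p stops at 5e-05, however, so at that floor the error grows with the fold change and largely fixes which genes are called. Egr1, Egr3, Sprr1a and Adamts1, at the floor in both genotypes with changes of the same sign, were not called. The count of 39 therefore does not measure stability. Lists called were 5, 6 and 2 for UV in p53KO, UV in p53CryKO and the difference; random matched lists called 8 in p53KO cells and 4 for the difference, and a preset correlation of 0.05 left 0 for the difference. Gained against random lists, which allow for no correlation among members, were the replication (p53KO cells), contractile and senescence lists in UV comparisons. In the difference, p53 targets (adjusted p = 0.00435) and endothelial markers (0.00435) were gained against random lists. The pseudocount of 1 gained collagens there (0.0251). Length adjustment called 7 lists in p53KO cells, gaining collagens (adjusted p = 0.0204) and mitochondrially encoded genes, and 6 in p53CryKO cells. Turned in direction were mitochondrially encoded genes in p53KO cells after length adjustment (adjusted p = 0.0258) and heat shock proteins in p53CryKO cells against random lists (0.0399).

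The correlation with length was -0.0430 in the middle and -0.139 in the highest tertile of FPKM in p53KO cells, and -0.204 in the lowest and -0.0736 in the middle one in p53CryKO cells. Over genes matched to GENCODE it was -0.323 and -0.368 with gene span and -0.377 and -0.434 with exonic length, and over protein-coding genes -0.256 and -0.301 with exonic length. The correlation between the genotypes was 0.938 at FPKM of 5 or more and 0.938 over called genes. At equal fragments and equal coding FPKM, log2 fold changes turned to -0.52 and -0.74 for Trp53, -0.54 and -0.77 for Cry1, -0.12 and -0.34 for Cdkn1a, -0.59 and -0.81 for Plk2, -0.49 and -0.72 for Rgs16 and -0.21 and -0.43 for Dusp8 in p53KO cells, and to -0.61 and -0.84 for Cry1 in p53CryKO cells. At equal coding FPKM alone they turned to -0.10 for Gm5560 and -0.71 for 9930013L23Rik in p53KO cells, and to -0.16 for Chchd2, -0.61 for Ranbp6 and -0.16 for Krt14 in p53CryKO cells. Krt19 turned to -0.0395 at equal coding FPKM in p53KO cells and to -0.23 and -0.46 in p53CryKO cells, and Tnnt2 to -0.0695 at equal coding FPKM in p53KO cells. These turns follow from the subtracted shift itself, and the cause of the other changes was not tested.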

Other observations

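Gene families chosen after seeing the data, so that their cameraPR p-values describe what prompted them, are given on the authors' scaling, those that moved first. Nuclear genes of oxidative phosphorylation, the respiratory chain and ATP synthase, gave 75 higher and 3 lower of 81 measured in p53KO cells (median 1.51, adjusted p = 4.05e-14) and 76 higher and 3 lower of 81 in p53CryKO cells (1.48, adjusted p = 1.82e-15). Mitochondrial ribosomal proteins gave 46 higher and 6 lower of 73 measured in p53KO cells (median 0.85, adjusted p = 2.12e-05) and 48 higher and 7 lower of 73 in p53CryKO cells (0.76, adjusted p = 5.59e-05). Proteasome subunits gave 27 higher and 2 lower of 37 measured in p53KO cells (median 1.04, adjusted p = 4.3e-05) and 29 higher and 0 lower of 37 in p53CryKO cells (0.82, adjusted p = 6.64e-05). Zinc finger genes named Zfp gave 24 higher and 116 lower of 201 measured in p53KO cells (median -0.88, adjusted p = 5.95e-07) and 17 higher and 125 lower of 191 in p53CryKO cells (-0.99, adjusted p = 5.09e-10). Hox genes, the homeobox regulators of body axis identity, gave 1 higher and 17 lower of 28 measured in p53KO cells (median -1.33, adjusted p = 6.29e-06) and 0 higher and 10 lower of 17 in p53CryKO cells (-0.88, adjusted p = 0.000756). Sm and LSm proteins of the spliceosome passed in p53CryKO cells (adjusted p = 0.0255) and not in p53KO cells (0.116). Aminoacyl-tRNA synthetases (adjusted p = 0.0553 and 0.174) and polyadenylated histone variants (0.888 and 0.5996) missed the threshold. The synthetase medians were 0.61 in p53KO and 0.39 in p53CryKO cells, with 14 and 13 of 18 log2 fold changes positive. Processed pseudogenes, which lack introns, gave 435 higher and 17 lower of 757 measured in p53KO and 536 higher and 9 lower of 820 in p53CryKO cells; their fragments can come from the parent genes. The medians of mitochondrial ribosomal proteins, and of proteasome subunits in p53CryKO cells, lie below the shift of equal coding FPKM and turn negative under it. They also lie below the medians of the shortest 10% of protein-coding genes by exonic length, 0.87 in p53KO and 0.93 in p53CryKO cells. The family tests were not adjusted for length, so whether these families moved apart from the trend with length was not tested.

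All tests of explanations in this part were chosen after the results were seen. Fold changes fell with length in both genotypes. A transcription block that grows with genomic span would leave a relation to span at equal exonic length, but the partial Spearman correlation among protein-coding genes was -0.0240 in p53KO and -0.0209 in p53CryKO cells, which argues against it as the whole cause. A bias limited to short transcripts would leave no trend among longer ones, but among coding genes of 2000 nt or more the correlation with exonic length was still -0.150 and -0.185. The same values are what loss of long RNA molecules needs, so that may contribute, although the labels give an RNA integrity number of at least 8. A limit of that reading is that the medians did not keep falling among the longest transcripts. Groups 9 and 10 of 10 by exonic length stood at -0.49 and -0.37 in p53KO and at -0.48 and -0.43 in p53CryKO cells. Differences in message stability with length, a biological explanation, were not tested.

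Some RNAs without a long poly(A) tail rose beside histone messages. Carry-over of more such RNA into the UV libraries would raise small RNAs beyond other short transcripts. In p53KO cells 64 of 80 measured snRNA, snoRNA and scaRNA models (80%) lay above the median gene, against 72.9% of the shortest 10% of coding genes (Fisher exact p = 0.190, two-sided), and in p53CryKO cells 78 of 87 (89.7%) against 75.4% (exact p = 0.00153). The share was higher in both but passed in p53CryKO cells only, and small RNAs are shorter than nearly all messages, so carry-over stays open. That limit of length does not cover mt-Rnr1 (955 nt) and mt-Rnr2 (1582 nt), whose lengths lie within those of the shortest 10% of coding genes. They rose by 7.31 and 5.29 in p53KO and by 6.70 and 4.30 in p53CryKO cells, against medians of 0.87 and 0.93 for those coding genes. As 2 of the largest rises they prompted the question and do not test it. Few of these models passed the authors' test on their own, 3 of 13 snRNA and 2 of 67 snoRNA and scaRNA models in p53KO and 3 of 15 and 3 of 72 in p53CryKO cells. As sets chosen after seeing the data and not adjusted for length, both were called as higher by cameraPR. The adjusted p was 5.38e-07 for snRNA and 7.14e-06 for snoRNA and scaRNA models in p53KO cells, and 2.13e-08 and 6.35e-12 in p53CryKO cells. More cells in S phase would raise replication genes as well, but their medians were -0.21 and 0.10, with upper quartiles of 0.62 and 0.69, below the histone medians. Replication genes thus did not rise as a list. How much S phase raises either group was not known, so setting them against histones cannot decide it, and more cells in S phase stays open. The trend with length is not the whole cause for histones, since their median after its removal was 1.45 and 0.79, still called in the list test (adjusted p = 0.000111 and 0.00674). Longer poly(A) tails on histone messages after UV, a biological explanation, were not tested.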
